A study of Mus musculus with 3 samples.

How the data were processed

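Total RNA from healing wound tissue was measured on 3 one-colour arrays, 1 each for day 10, day 12 and day 14 after wounding. Per the labels' protocols, tissue of 3 mice was combined for each day, and 250 ng of total RNA was amplified, turned into cDNA, fragmented and labelled with biotin. The groups were taken from the time given in the labels. The table used here holds 1 log2 expression value per probe set and array, as deposited by the authors, and the RMA method and Partek 6.6 are named in the submitters' processing notes without their roles. That the values are on a log2 scale was taken from their range, which runs from 4.37 to 14.1. No genome build was used, and no coordinates are given. No scanner output was used here, so background and detection per probe set are unknown.

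Each array's median over all 35556 probe sets was 7.53, 7.55 and 7.53, and values were used as deposited without further scaling. Of the probe sets, 8221 (23.1%) held exactly the same value on all 3 arrays, and 17167 (48.3%) held the same value on at least 2 of them. The share with 3 equal values was 40.8% in the 25% of probe sets with the lowest mean and 11.2% in the 25% with the highest. Medians taken over the probes of a probe set, as in RMA's median polish, can return equal values when few arrays are summarised, and a difference of 0.00 is therefore not a precise measurement of no difference. Among the 9969 genes compared, the difference was exactly 0 for 21.1% on day 12 against day 10, 24.8% on day 14 against day 12 and 16.6% on day 14 against day 10.

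Gene symbols came from the platform's annotation. It gave 1 gene symbol for 21789 probe sets and several for 1621, and it did not list 12146. Only probe sets with 1 symbol were used. A match by Entrez identifier to a gene table of the GRCm38.p6 assembly covered 21698 of the 21789 and changed 0 symbols. Values of probe sets of the same gene were averaged, giving 19938 genes. Of these, 999 had several probe sets. For each of 627 genes, the difference between days of a probe set was set against the mean of a pair of that gene's probe sets. The spread between probe sets is the robust standard deviation of this deviation over genes. It was 0.03 on day 12 against day 10, 0.03 on day 14 against day 12 and 0.05 on day 14 against day 10. The 95th percentiles of the deviation's size were larger, at 0.17, 0.14 and 0.20. This spread covers technical spread within an array and not the spread between animals. The 13767 probe sets left out of the gene counts held 27 that were at least 2-fold higher and 4 at least 2-fold lower on day 12 against day 10, 5 and 22 on day 14 against day 12, and 34 and 30 on day 14 against day 10.

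The level filter kept the 9969 genes whose highest value over the 3 arrays was at or above the median of that quantity, 8.36. A gene could pass by its value on a single day, so the members of a list depended in part on the differences compared. The 3 pairs of days were compared by the log2 difference. Since each day had 1 array, no test across genes was made and no p-value is given, and no difference has a replicate check. Genes were counted by a fixed size of 2-fold. For each of 35 gene lists written before the data were examined, the median difference of the members above the filter was set against 10000 random lists of the same size drawn from genes in the same of 20 bins of mean expression. The percentile describes these arrays only, since genes are not replicates, and it was computed for lists of 5 or more members. Some genes belong to more than 1 list, for instance Fa2h, Sostdc1, Des, Mmp8 and Ppbp. A gene was said to lie between days when its value on the remaining day lay strictly between the other values, and intervals for such shares are exact (Clopper-Pearson) at 95%.

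The genes named in the text followed a rule written before the data were examined. For each pair of days these were the 12 genes with the largest increase and the 12 with the largest decrease above the filter, leaving out symbols of predicted genes, olfactory, vomeronasal and taste receptors, small RNAs and single antigen receptor segments. For each list they were the 4 members with the largest absolute difference between day 14 and day 10. Fgf9, Shh, Lef1, Wnt10b, Edar, Krt17, Krt6a, Col1a1, Col3a1, Acta2 and Mki67 were named whatever their values. Other genes are said to have been chosen after their values were seen.

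Alternatives fixed before the data were examined were no level filter, a filter on the mean in the top 25% of genes, arrays centred on their medians over genes, quantile normalization, cyclic loess, the brightest probe set per gene, and a 1.5-fold threshold. Chosen after seeing the data were the count of a tied day as lying between the others, the removal of genes with identical values, and the shuffling of each gene's values over days. The counting and list steps were tested on simulated data for day 14 against day 10 over 9969 genes. Of 200 genes changed by 1.5 log2 units, 98.5% were counted, with 0 of the wrong sign and 0 unchanged genes counted. Of 10 lists shifted by 0.3, 10 lay above percentile 97.5, and 0 of 40 unshifted lists lay outside percentiles 2.5 to 97.5. The simulated noise was independent between genes and of a fixed size, small beside 1.5, and was not estimated from replicates. These results therefore check the steps only and give no error rate for the counts in these data. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3 with limma 3.58.1.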

Results

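Gene expression was measured in healing back skin of C57Bl/6 mice, an inbred laboratory strain, at 6 weeks of age. Each animal had received a large wound of 1.5 cm2 through the full thickness of the skin, so that epidermis and dermis were both removed. The healing tissue was collected on day 10, day 12 or day 14 after wounding, and tissue around the wound and hair follicles at its edge were avoided during dissection, per the labels. Tissue of 3 mice was combined for each day, and each pool was hybridised to 1 one-colour array. There was thus 1 value per gene and day, no replicate error could be estimated, and every difference given here compares single pools. The number of arrays limits the precision. The median log2 expression over 35556 probe sets was 7.53 on day 10, 7.55 on day 12 and 7.53 on day 14. Pearson's r across probe sets, which are not independent replicates, was 0.994 between day 10 and day 12, 0.996 between day 12 and day 14, and 0.991 between day 10 and day 14. Of 19938 named genes, the 9969 whose highest value over the 3 arrays reached 8.36 log2 units were compared, and differences are log2 differences or the fold sizes they correspond to.

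The comparison of day 12 with day 10 asked which transcripts differed between the first pair of days. Genes of the cornified epidermis and of the sebaceous gland were higher on day 12, together with genes of dendritic cells and interferon responses and some mast cell genes. The myofibroblast, cell cycle and endothelial lists were lower, while the pericyte and smooth muscle list stayed inside the range of random lists. Of the 9969 genes, 148 were at least 2-fold higher on day 12 and 18 were at least 2-fold lower. With the filter restricted to genes whose mean lay in the top 25%, these counts were 55 and 4.

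Each of the 32 cornified epidermis genes above the level filter was higher on day 12 than on day 10, with a median difference of 0.54 (interquartile range 0.35 to 0.79). This median was at percentile 100 of 10000 random gene lists of the same size matched on mean expression. Krt77, a keratin of the differentiated layers, was 5.16-fold higher, and Flg2, a filaggrin-family protein of the cornified envelope, was 4.01-fold higher. Lce1f and Lce1b, which encode late cornified envelope proteins, were 2.40-fold and 1.89-fold higher. The 16 basal epidermis genes had a median difference of 0.02, at percentile 92.4. Among them, the keratin gene Krt15 was 2.43-fold higher, whereas Col17a1, Trp63 and Cdh3 differed by 0.43, 0.29 and −0.15. The 22 genes of activated keratinocytes split evenly, with 11 higher, 10 lower and a median of 0.01. In that list, the serpin gene Serpinb3a was 3.62-fold higher, the interleukin 36 gene Il1f6 was 2.11-fold higher, and Defb3 and Stfa3 differed by 0.85 and 0.89. The wound keratin genes Krt17 and Krt6a differed by −0.01 and −0.04.

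Of 16 sebaceous gland genes, 11 were higher on day 12, and 6 of these were at least 2-fold higher. Their median difference was 0.55 (interquartile range −0.14 to 1.47), at percentile 100. Elovl3 and Fa2h, which act in fatty acid elongation and hydroxylation, were 5.02-fold and 4.78-fold higher. Far2, a fatty acyl-CoA reductase gene, was 4.29-fold higher, and the keratin gene Krt79 was 3.54-fold higher. The other 5 members were lower, and the median was 0.03 when only genes whose mean lay in the top 25% were used. Lists of other structures of intact skin were higher on the same array. The medians were 0.37 for 9 genes of hair shaft and inner root sheath, 0.29 for 7 adipocyte genes and 0.20 for 10 genes of Schwann cells and nerves, of which Fa2h also belongs to the sebaceous list. They lay at percentiles 99.97, 99.6 and 99.6, and were 0.09, 0.00 and 0.09 with no level filter. Lpl, Cebpa and Pparg of the adipocyte list differed by 0.64, 0.55 and 0.29, whereas Nnat differed by −0.43. In the nerve list, Gfra3 and L1cam differed by 0.80 and 0.68 and Mal by −0.92. The 7 skeletal muscle genes above the filter had a median of −0.25, and of them Des, Acta1, Actc1 and Tnnt2 differed by −0.70, −0.71, −0.34 and −0.13. Without the filter, the median over all measured muscle genes was 0.00.

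The Y-linked genes Eif2s3y and Uty were at least 17.1-fold and 11.4-fold higher on day 12. These are lower bounds, because both genes stood at 5.49 on day 10, below that array's lower quartile of 5.91. The transcript Xist, which is made from the inactive X chromosome and was looked up after these values were seen, was 12.3 on day 10, 12.0 on day 12 and 12.3 on day 14. The labels used here give no sex. The epidermal lipoxygenase genes Alox8 and Alox12e were 7.11-fold and 5.92-fold higher. Skint9, of a family of immunoglobulin-like proteins of the epidermis and thymus, was 6.92-fold higher, and Clca3a2 was 6.42-fold higher. The remaining genes named by size were Cyp2g1 at 5.63-fold, Aadac at 5.62-fold and Orm1, an acute-phase glycoprotein gene, at 5.17-fold.

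Immune genes were mostly higher on day 12. Of 28 interferon-stimulated genes, 24 were higher, with a median difference of 0.38 at percentile 100. The chemokine gene Cxcl9 was 3.76-fold higher, Ifi205 and Rtp4 differed by 0.78 and 0.24, and Cxcl10 differed by −0.22. Of 19 dendritic and Langerhans cell genes, 17 were higher and none was lower, with a median of 0.38 at percentile 100. Epcam, an adhesion molecule of Langerhans cells and some epithelial cells, was 2.34-fold higher, and Itgax, which encodes CD11c, was 2.09-fold higher. Mgl2 was 2.08-fold higher and Cd209d differed by 0.71. They stood at 6.94 and 7.39 on day 10 and passed the filter only by their day 14 values. The dendritic median was 0.32 with no level filter. The macrophage and monocyte list had 27 of 30 genes higher, with a median of 0.27 at percentile 100. The neutrophil list had 10 of 14 genes higher and a median of 0.44, which was 0.00 with no level filter. Of 32 cytokine and chemokine genes, 8 were at least 2-fold higher and Cxcl5, a neutrophil attractant gene, was 2.15-fold lower. The median was 0.28, and it was 0.05 with no level filter. The interleukin gene Il1a was 2.21-fold higher. In the mast cell list of 7 genes, the protease genes Mcpt4 and Cpa3 were 2.45-fold and 2.43-fold higher, Tpsb2 differed by 0.89, and Mcpt2 differed by −0.51. The median of that list was 0.43, and 0.16 with no level filter. The mast cell median lay at percentile 99.8, with 4 of the 7 genes higher, 1 lower and 2 exactly equal. The 11 T cell genes had a median of 0.11, at percentile 98.8, and 0.06 with the brightest probe set per gene. Among them, Thy1 differed by −0.33, Cd5 by 0.27, Il2rb by 0.53 and Il7r by 0.14. On the same array, 20 of 26 immediate early genes were higher than on day 10, with a median of 0.17 at percentile 100, and 0.34 with the filter on the top 25%. Egr2 was 2.15-fold higher, Klf4 and Btg2 differed by 0.45 and 0.50, and Nr4a2 by −0.29.

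The smooth muscle genes Cnn1 and Actg2, which encode calponin 1 and gamma 2 actin, were 3.70-fold and 3.41-fold lower. In the list of 26 myofibroblast genes, 20 were lower, with a median of −0.21 at percentile 0.0. Myl9, Tagln and Acta2, all encoding parts or regulators of the contractile apparatus, differed by −0.98, −0.80 and −0.54. Of 51 cell cycle genes, 45 were lower, with a median of −0.30 at percentile 0.0. None of these genes reached 2-fold. The mitotic genes Kif2c, Cdca3, Nuf2 and Bub1 differed by −0.63, −0.59, −0.57 and −0.46, whereas Mki67 differed by 0.01. Of 28 endothelial genes, 25 were lower, with a median of −0.22 at percentile 0.01. Plvap, which encodes a protein of endothelial diaphragms, was 2.01-fold lower, and Sox18, Esam and Apln differed by −0.77, −0.55 and −0.08. The 16 genes of dermal condensate and papilla had a median of −0.25, which was −0.03 with no level filter. The other genes named for being lower were Cdh10, Cck, Fibin, Ecrg4, Epgn, Wnt2b, Defb14, Lrg1, Rpp25 and Rasl11b. They lay between the 2.58-fold of Cdh10 and the 2.17-fold of Rasl11b.

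Lists for signalling and matrix had medians nearer to 0. The medians on day 12 against day 10 were 0.00 for 30 Wnt pathway genes, −0.02 for 15 Fgf pathway genes, −0.11 for 8 hedgehog genes, −0.07 for 28 Tgf-beta and Bmp genes and −0.03 for 49 collagen and matrix genes. They were 0.00 for 27 matrix proteases and inhibitors, 0.09 for 14 prostaglandin genes, 0.06 for 27 genes of hypoxia and glycolysis, 0.13 for 13 hair placode and germ genes, 0.09 for 6 lymphatic genes and −0.02 for 13 pericyte genes. The placode, hypoxia and prostaglandin medians lay at percentiles 99.5, 99.8 and 99.0, and the others in this group lay inside the central 95% of random lists. The placode and prostaglandin medians were 0.01 and 0.01 with no level filter, and the Tgf-beta and Bmp median was −0.03. The hair placode median turned to −0.01 when only genes whose mean lay in the top 25% were used. The 23 housekeeping genes had a median of 0.00. Single members stood apart from these medians. Sfrp4, which encodes a secreted Wnt antagonist, was 3.31-fold higher, and Tnfrsf19, a receptor gene that is a Wnt target, was 2.72-fold higher. Sostdc1, an antagonist of Bmp and Wnt signalling, was 2.15-fold higher, Fgf22 was 2.31-fold higher, and the elastin gene Eln was higher by 1.32. Id4, a target of Bmp signalling, was 2.12-fold higher, whereas Wnt2b was 2.41-fold lower. The main fibrillar collagen genes Col1a1 and Col3a1 differed by 0.00 and 0.035.

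The comparison of day 14 with day 12 asked which transcripts differed between the second pair of days. Genes of neutrophils, macrophages and inflammatory chemokines were lower on day 14, and a few keratin and hair genes were higher. Of 9969 genes, 36 were at least 2-fold lower on day 14 and 3 were at least 2-fold higher. With no level filter the 3 became 11, and with the filter on the top 25% the counts were 11 lower and 1 higher.

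The neutrophil attractant genes Cxcl3 and Cxcl2 were 6.48-fold and 5.13-fold lower on day 14 than on day 12. Mmp8, the neutrophil collagenase gene, was 5.37-fold lower, and Trem1, an activating receptor gene of myeloid cells, was 4.41-fold lower. Ppbp, a chemokine gene of platelets, was 4.52-fold lower, Il1b was 2.95-fold lower, and Nos2 and Ptgs2, which encode inducible nitric oxide synthase and cyclooxygenase 2, were 3.65-fold and 3.85-fold lower. In the neutrophil list, 12 of 14 genes were lower and 5 were at least 2-fold lower, with a median of −0.67 at percentile 0.0. This median was −0.11 with no level filter. Mmp9 in that list differed by −0.72. In the macrophage and monocyte list, 27 of 30 genes were lower, with a median of −0.24 at percentile 0.0. Cd14, a receptor gene for bacterial lipopolysaccharide, and Arg1 were 2.58-fold and 2.39-fold lower, Pf4 differed by −0.98, and Lyz1 differed by 0.34. Of 28 interferon-stimulated genes, 26 were lower, with a median of −0.37 at percentile 0.0 and none at 2-fold. In that list, Rtp4, Cxcl10, Cxcl9 and Ifi205 differed by −0.67, −0.64, −0.57 and −0.22. Of 32 cytokine and chemokine genes, 24 were lower and 6 were at least 2-fold lower, with a median of −0.32 that was −0.01 with no level filter. The interferon-inducible gene Slfn4, the stromelysin gene Mmp10, the acute-phase gene Saa3 and the cornified envelope gene Lce3a were 3.41-fold, 3.16-fold, 3.12-fold and 2.97-fold lower. Within the 27 matrix proteases and inhibitors, 3 genes were at least 2-fold lower and the median was −0.09, at percentile 0.19. It was −0.05 with no level filter and −0.05 under quantile normalization. Hmox1, the heme oxygenase gene in the hypoxia list, differed by −0.99, beside a list median of −0.08 at percentile 1.14 that was −0.04 under quantile normalization.

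**Figure D1:**
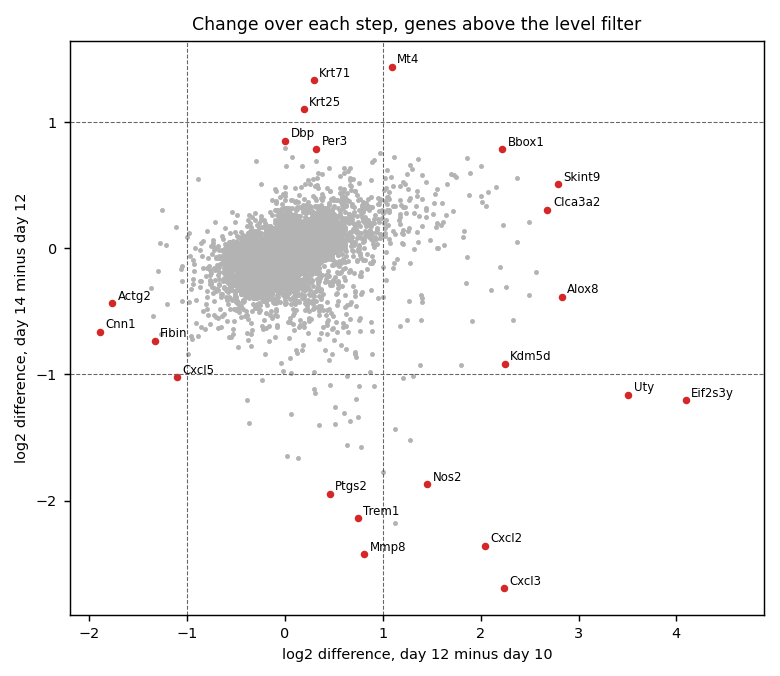
Log2 difference of day 14 minus day 12 (vertical axis) against day 12 minus day 10 (horizontal axis) for the 9969 genes above the level filter, 1 point per gene and 1 pool of mice per day. Dashed lines mark 2-fold, and red points are named genes, of which Kdm5d was chosen after its values were seen. Cxcl3 and Cxcl2 lie at lower right, higher by 2.24 and 2.05 on day 12 and then differing by −2.70 and −2.36 on day 14, whereas Cnn1 and Actg2 lie at lower left.

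The 3 genes at least 2-fold higher on day 14 than on day 12 were Mt4, Krt71 and Krt25, at 2.71-fold, 2.52-fold and 2.15-fold. Krt71 and Krt25 are keratin genes of the inner root sheath of the hair follicle, and Mt4 is a metallothionein gene of stratified epithelium. All of them belong to the list of hair shaft and inner root sheath, of which 9 of 35 measured genes passed the level filter. In this list 7 of 9 genes were higher, with a median of 0.37 at percentile 100, and Tchh, the trichohyalin gene, differed by 0.48. Krt71, Krt25 and Tchh stood at 8.18, 7.48 and 8.04 on day 12 and passed the filter of 8.36 only by their day 14 values, so that membership depended in part on the difference itself. The median was 0.32 with no level filter. The other genes named for being higher did not reach 2-fold. Dbp and Per3, which are genes of the circadian clock, were 1.81-fold and 1.73-fold higher. Adh1, Bbox1, Ano7, Car6, Hsd17b2, Serpinb7 and Cpm lay between 1.74-fold for Adh1 and 1.63-fold for Cpm.

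The lists of the cornified epidermis, dendritic cells, mast cells, adipocytes and nerves, which had been higher on day 12, had medians of smaller size between day 12 and day 14. The median was 0.07 at percentile 100 for the cornified epidermis, −0.01 for dendritic and Langerhans cells, 0.08 at percentile 98.8 for mast cells, 0.00 for adipocytes and 0.03 for Schwann cells and nerves. The basal epidermis, which had a median near 0 on day 12 as well, had a median of 0.01, at percentile 99.5, and 0.04 under quantile normalization. The dendritic median was 0.02 after each array was centred on its median. The sebaceous median was −0.09 at percentile 2.18 and was −0.02 without genes of identical values, and it turned to 0.04 when only genes whose mean lay in the top 25% were used. Elovl3, Far2 and Fa2h differed by −0.57, −0.33 and −0.31, and Eif2s3y and Uty were 2.31-fold and 2.24-fold lower than on day 12. The myofibroblast, cell cycle, endothelial and dermal papilla lists, which had been lower on day 12, had negative medians again on day 14. Each of the 26 myofibroblast genes was lower on day 14, with a median of −0.20 at percentile 0.0. In the cell cycle list, 39 of 51 genes were lower and 9 had exactly equal values, with a median of −0.08 at percentile 0.02 that was −0.05 under quantile normalization. The medians were −0.07 for endothelium, at percentile 2.26, and −0.20 for dermal condensate and papilla, in which the keratinocyte growth factor gene Fgf7 was 2.07-fold lower. The endothelial median was −0.03 under quantile normalization. It was −0.04 and the dermal papilla median 0.00 with no level filter. The remaining lists had medians of 0.06 for Wnt, 0.00 for Fgf, −0.05 for hedgehog, −0.02 for Tgf-beta and Bmp, −0.05 for collagens and matrix, −0.08 for activated keratinocytes, −0.01 for hair placode and germ, −0.12 for prostaglandin genes, 0.00 for T cells, −0.11 for lymphatic endothelium, −0.06 for pericytes, 0.00 for skeletal muscle, −0.03 for immediate early genes and 0.00 for housekeeping genes. The Wnt, activated keratinocyte and prostaglandin medians lay at percentiles 100, 1.99 and 0.42, and those of the other remaining lists inside the central 95% of random lists. The Wnt median ran from 0.03 with the filter on the top 25% to 0.13 without genes of identical values, and the activated keratinocyte median was −0.04 under quantile normalization. The hedgehog, Tgf-beta and prostaglandin medians were 0.00 with no level filter. The sign of the immediate early median turned under quantile normalization, to 0.01, and that of the Tgf-beta and placode medians turned after each array was centred, to 0.0022 and 0.02.

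The comparison of day 14 with day 10 spanned the whole interval sampled. On day 14, the cornified epidermis, sebaceous and hair shaft lists were higher, and the myofibroblast, cell cycle, endothelial and dermal papilla lists were lower. Of 9969 genes, 223 were at least 2-fold higher and 91 were at least 2-fold lower. With the filter on the top 25% the counts were 88 and 31, and at a 1.5-fold threshold they were 525 and 517. Of the 314 genes past 2-fold, 283 had their day 12 value between the other days, a share of 90.1% with an exact binomial 95% confidence interval of 86.3 to 93.2% that treats genes as independent. When the 3 values of each gene were shuffled over the days 100 times, the mean share was 67.2% and the highest was 76.3%. Day 14 lay between day 10 and day 12 for 38 of the 166 genes past 2-fold on day 12 against day 10 (22.9%, interval 16.7 to 30.0%), and day 10 lay between day 12 and day 14 for 28 of 39 genes (71.8%, interval 55.1 to 85.0%). The last share was 45.0% at a 1.5-fold threshold.

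Among the genes with the greatest excess on day 14, Skint9 was 9.84-fold higher than on day 10, and Skint10 and Skint4 of the same family were 6.22-fold and 5.64-fold higher. Bbox1, which encodes the last enzyme of carnitine synthesis, was 8.03-fold higher, Clca3a2 7.94-fold, and Orm1 7.60-fold, and Aadac was higher by 2.70. The Y-linked gene Eif2s3y was at least 7.41-fold higher. In the cornified epidermis list, 30 of 32 genes were higher and 6 were at least 2-fold higher, with a median of 0.50 at percentile 100. Flg2 was 6.30-fold higher and Krt77 was 5.33-fold higher, followed by Lce1f at 2.68-fold and Lce1b at 2.27-fold. Serpinb7, a serpin gene of the upper epidermis, was 5.98-fold higher, and Cyp17a1, which encodes a steroid hydroxylase, was 5.72-fold higher. The basal epidermis had a median of 0.03 at percentile 98.3, and 0.06 under quantile normalization, with Krt15 at 3.84-fold and Col17a1, Trp63 and Cdh3 at differences of 0.65, 0.42 and −0.47. The activated keratinocyte list had a median of −0.11, with 14 genes lower and 8 higher, and its mean was 0.10. Serpinb3a, Defb3 and Il1f6 in that list were 3.45-fold, 2.36-fold and 2.18-fold higher, and Krt17 and Krt6a differed by −0.02 and −0.11. For Krt17 and Krt6a, bright probes may again hide a change.

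Of the 16 sebaceous genes, 5 were at least 2-fold higher on day 14 and 1 was at least 2-fold lower, with a median of 0.57 at percentile 100 that was 0.07 with the filter on the top 25%. The sebaceous median was 0.42 with no level filter. Fa2h, Krt79, Far2 and Elovl3 were 3.86-fold, 3.77-fold, 3.42-fold and 3.38-fold higher. Each of the 9 hair shaft and inner root sheath genes above the filter was higher, with a median of 0.58 at percentile 99.99. With no level filter this median was 0.36. Krt71, Krt25 and Tchh stood at 7.89, 7.29 and 7.61 on day 10 and passed the filter only by their day 14 values. That all 9 were higher is thus in part a result of the filter. Mt4 was 5.77-fold higher, Krt71 3.08-fold, Krt25 2.45-fold and Tchh 1.88-fold. The adipocyte, nerve and skeletal muscle medians beside these were 0.35, 0.25 and −0.18. They lay at percentiles 99.8, 99.7 and 14.8, and were 0.06, 0.12 and 0.00 with no level filter. The dendritic and Langerhans cell median was 0.34 at percentile 100, with Epcam at 2.94-fold, Mgl2 at 2.74-fold, Itgax at 2.58-fold and Cd209d at 2.24-fold. In the mast cell list, Mcpt4, Cpa3 and Tpsb2 were 3.79-fold, 3.20-fold and 2.97-fold higher and Mcpt2 differed by −0.89, beside a median of 0.08 over 7 genes.

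**Figure D2:**
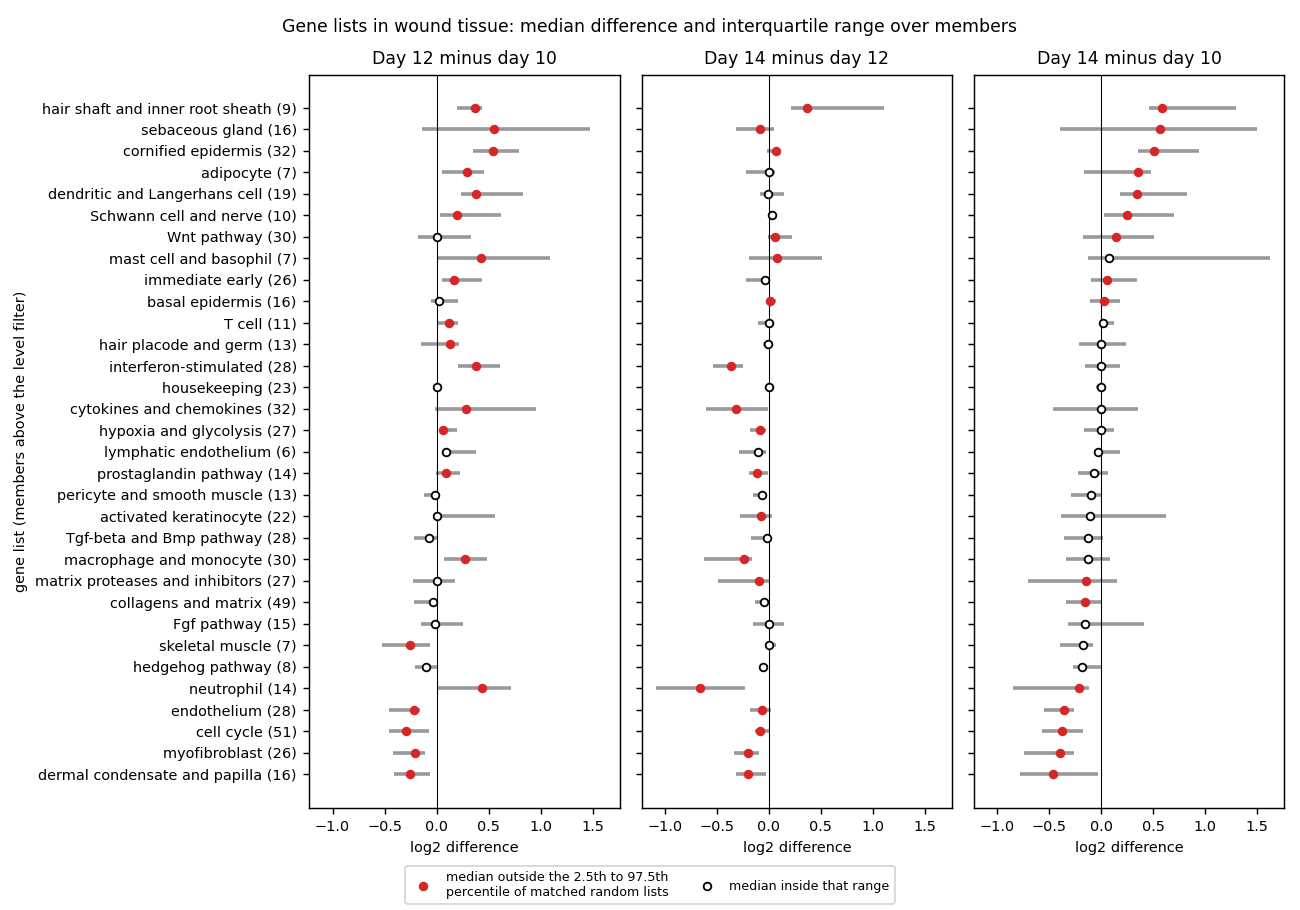
Median log2 difference (points) and interquartile range over members (bars) for 32 gene lists in each of the 3 comparisons, with the number of members above the level filter in brackets and 1 array per day. Red points are medians outside the central 95% of 10000 random lists matched on expression, a description of these arrays and not a test. On day 14 against day 10 the hair shaft and sebaceous lists are highest, at 0.58 and 0.57, and the dermal condensate and myofibroblast lists are lowest, at −0.46 and −0.40. Some hair shaft and sebaceous genes passed the filter only by a later value. With no level filter the hair shaft, sebaceous and dermal condensate medians were 0.36, 0.42 and −0.03.

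Cnn1 and Actg2 were 5.85-fold and 4.61-fold lower on day 14 than on day 10. All 26 myofibroblast genes were lower, with a median of −0.40 at percentile 0.0. Myl9 was 2.65-fold lower, Tagln 2.20-fold and Acta2 1.83-fold. Desmin, encoded by Des, was 2.06-fold lower, beside a median of −0.10 at percentile 19.0 over 13 pericyte and smooth muscle genes in which Mcam, Rgs4 and Pdgfrb differed by −0.60, −0.46 and −0.29. In the cell cycle list, 49 of 51 genes were lower, with a median of −0.37 at percentile 0.0 and none at 2-fold. Kif2c, Nuf2, Bub1 and Cdca3 differed by −0.87, −0.80, −0.74 and −0.72, and Mki67 by −0.11. In the endothelial list, 24 of 28 genes were lower, with a median of −0.36 at percentile 0.0. Sox18, a transcription factor gene of endothelium, was 2.03-fold lower, and Plvap, Esam and Apln differed by −0.91, −0.70 and −0.69. Lymphatic endothelial genes had a median of −0.03, with Reln, Flt4, Tbx1 and Lyve1 at 0.45, −0.31, 0.24 and −0.07. Other genes named for being lower were Cxcl5 at 4.37-fold, Fibin at 4.18-fold, Wnt2b at 3.85-fold, Cck at 3.70-fold, Gria1 at 3.55-fold and Clec2e at 3.38-fold. They were followed by Cdh10, Stra6, Rpp25 and the desmocollin gene Dsc2, between 3.22-fold for Cdh10 and 3.15-fold for Dsc2.

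The dermal condensate and papilla list had a median of −0.46 at percentile 0.0, with 12 of 16 genes lower. This median was −0.03 with no level filter. Fgf7 was 2.43-fold lower, Tbx18 differed by −0.92, and Sostdc1 was 2.71-fold higher. The hair placode and germ list had a median of 0.00 over 13 genes, and 0.14 with no level filter. In it Tnfrsf19 was 3.90-fold higher, and Wnt10a and Sox9 differed by 0.50 and −0.60. The signalling genes Fgf9, Shh, Lef1, Wnt10b and Edar, which take part in hair follicle formation and were named before the data were examined, all lay below the level filter on every day. Fgf9 was at 7.05, 7.12 and 7.25 on days 10, 12 and 14, and Shh at 7.10, 7.10 and 7.34. Lef1 and Wnt10b differed by 0.02 and 0.09 between day 14 and day 10, and Edar was 6.53 on each day.

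**Figure D3:**
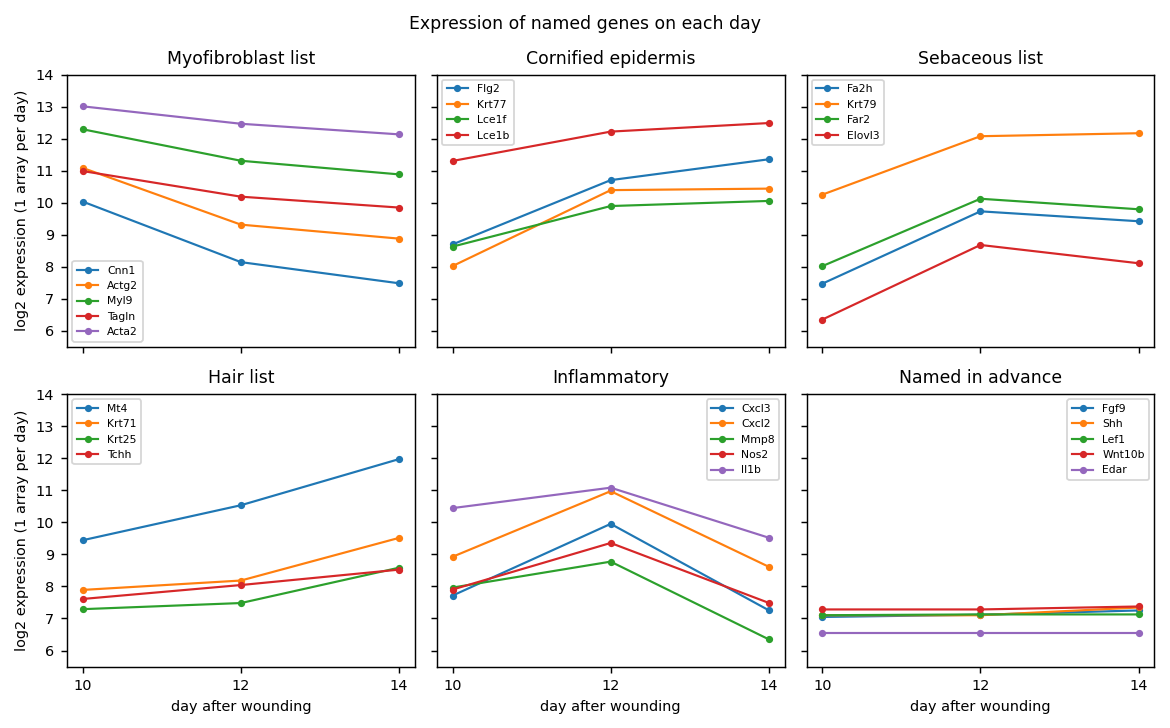
Log2 expression (vertical axis) of named genes on days 10, 12 and 14 after wounding (horizontal axis), 1 pool of mice and 1 array per point, with lines joining the values of a gene. Cnn1 goes from 10.0 to 8.15 and 7.49, Cxcl3 goes from 7.71 to 9.95 and 7.25, and Fgf9 goes from 7.05 to 7.12 and 7.25.

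Wnt pathway genes had a median of 0.15 on day 14 against day 10 over 30 genes, at percentile 100. This was 0.24 without genes of identical values and turned to −0.14 when only genes whose mean lay in the top 25% were used. Sfrp4 was 4.95-fold higher and Wnt2b was 3.85-fold lower. Fgf pathway genes had a median of −0.16 over 15 genes and a mean of 0.07, and the median was 0.00 with no level filter. Fgf22 and the receptor gene Fgfr4 were 2.51-fold and 2.47-fold higher, and Fgfr3 differed by 0.88. Hedgehog genes had a median of −0.19, at percentile 7.89, with Gas1, Smo, Gli3 and Gli2 at −0.30, −0.28, −0.27 and −0.22. Their median was −0.0046 with no level filter. In the Tgf-beta and Bmp list, with a median of −0.13, Id4 was 3.14-fold higher, and Grem1, a Bmp antagonist gene, and Tgfb2 were 2.04-fold and 2.01-fold lower. Inhba differed by −0.85, and the list's median was −0.03 with no level filter. Of 49 collagen and matrix genes, 37 were lower, with a median of −0.15 at percentile 0.08 that was −0.09 with no level filter. Against that median, Eln was higher by 1.32 and Prelp was 2.31-fold higher, Efemp1 differed by 0.97, and the lysyl oxidase-like gene Loxl3 was 2.32-fold lower. Col1a1 was 13.5 on each day, and Col3a1 differed by 0.035, although bright probes may hide a change in both. Matrix proteases and inhibitors had a median of −0.15 at percentile 1.84, and −0.10 with no level filter. Mmp8, Mmp10 and Adamts6 were 3.06-fold, 2.88-fold and 2.43-fold lower, and the inhibitor gene Timp3 was 2.44-fold higher.

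The neutrophil, macrophage, interferon and cytokine lists were near or below their day 10 values on day 14. The medians against day 10 were −0.22 for neutrophils, at percentile 2.17, −0.13 for macrophages and monocytes, 0.00 for interferon-stimulated genes and 0.00 for cytokines and chemokines. The neutrophil median was −0.34 with the filter on the top 25% and −0.11 with no level filter, where the macrophage median was −0.08. Trem1, Mmp9 and Ppbp were 2.63-fold, 2.15-fold and 2.08-fold lower on day 14 than on day 10, and Il1b, Arg1, Cd14 and Pf4 differed by −0.92, −0.75, −0.70 and −0.68. Cxcl9 and Il1a were 2.52-fold and 2.09-fold higher, whereas Cxcl10 differed by −0.87. The remaining medians were 0.02 for T cells, −0.07 for prostaglandin genes, −0.00 for hypoxia and glycolysis, 0.05 at percentile 99.9 for immediate early genes and 0.00 for housekeeping genes. The immediate early median was 0.19 with the filter on the top 25% and 0.10 under quantile normalization. The prostaglandin median was 0.00 with no level filter. Ptgs2 in that list was 2.81-fold lower, while Alox5, Hpgd and Alox5ap differed by 0.48, 0.37 and −0.28. Hmox1, Car12, Egln3 and Slc16a3 in the hypoxia list differed by −0.93, 0.65, 0.64 and −0.55, and the housekeeping genes Vps29, Psmb2, Reep5 and Psmb4 by −0.38, −0.19, −0.18 and −0.14. For 3 lists only 2 genes passed the filter and no median was taken. These genes differed by 0.17 for Blnk and −0.14 for Xbp1 of B and plasma cells, and by −0.06 for Ednrb and 0.00 for Kit of melanocytes. In the erythrocyte and platelet list they were Ppbp and Pf4.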

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

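Counting a tied day as lying between and leaving out genes with identical values were chosen after seeing the data, and the other settings before. No paired analysis was possible because each day had 1 array, and no array could be left out. With no level filter, 11 genes were at least 2-fold higher on day 14 than on day 12. With the filter on genes whose mean lay in the top 25%, which tests fewer genes, 55 were higher and 4 lower on day 12 than on day 10, 1 higher and 11 lower on day 14 than on day 12, and 88 higher and 31 lower on day 14 than on day 10. At 1.5-fold, which is a lower bar by construction, the pairs of counts were 416 and 163, 32 and 119, and 525 and 517, and the share of genes with day 10 between day 12 and day 14 was 45.0%. The other 58 values of counts and shares stayed within 1.5 times the original count, or for shares within its interval. Among list medians outside the central 95% of random lists, 3 changed sign, all under the filter on the top 25%. These were hair placode and germ on day 12 against day 10 (−0.015), the sebaceous gland on day 14 against day 12 (0.036) and the Wnt pathway on day 14 against day 10 (−0.14), and the cause was not tested beyond the change of members. Of the other list medians over all settings, 479 moved by no more than the standard deviation of their random lists' medians and 154 by more. A further 18 of these values changed sign, from medians no larger in size than 0.035. For named genes, 1216 differences moved by no more than the spread between probe sets and 42 by more, all 42 under quantile normalization. Most of the 1216 could not have moved. Filters and the removal of genes leave a gene's value as it is, and each named gene had 1 probe set. Centring shifts all genes alike, by less than that spread. Only cyclic loess, with 200 unmoved, and quantile normalization, with 158 unmoved, put these differences to a test. Of all differences of named genes 5 changed sign, those of Lef1, Krt17 and Col1a1 between day 14 and day 10, none larger in size than 0.025. Signal over background is unknown for these values, and the single array per day limits all of them.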

Other observations

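The gene families in the first paragraph, the shuffling over days, the tests of male mice among female mice, all tests of the cornified and sebaceous pattern, and the choice of all 3 patterns came after the values were seen. Members of 2 families of the outer epidermis moved in different directions. The 7 measured Skint genes had a median difference of 1.63 between day 14 and day 10. All 4 above the level filter were at least 2-fold higher, but Skint4, Skint9 and Skint10 passed it only by their later values, and Skint2 and Skint7, below it, differed by 0.62 and 0.999. Of the Lce3 genes, a group of late cornified envelope genes known to be induced by epidermal damage, 4 passed the filter. Lce3a, Lce3c, Lce3e and Lce3f were 0.78, 0.11, 0.72 and 0.51 higher on day 12 than on day 10, and then differed by −1.57, −0.80, −1.20 and −1.40 between day 12 and day 14. Their median on day 14 against day 10 was −0.74, while Lce1f and Lce1b were 1.42 and 1.18 higher. Of 7 lipoxygenase genes, Alox8, Alox12e and Aloxe3 were higher on day 14 than on day 10 by 2.45, 2.38 and 1.02, while Alox12b, Alox5, Alox12 and Alox15 differed by 0.49, 0.48, 0.39 and 0.18.

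The differences of the first and the second step were weakly correlated across genes. The correlation across the 9969 genes of the difference from day 10 to day 12 with that from day 12 to day 14 was 0.21, with a covariance of 0.012. Both steps share the day 12 array with opposite signs, so chance alone pulls this correlation below 0. When the values of each gene were shuffled over days 100 times, the mean correlation was −0.50 and the highest −0.46, with a mean covariance of −0.048. Genes are not independent replicates, and shuffling also breaks up real differences between days. Single lists went against this correlation, as the neutrophil medians of 0.44 and then −0.67 and the interferon medians of 0.38 and then −0.37 show.

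Y-linked genes were much higher on day 12 and day 14 than on day 10. Eif2s3y stood at 5.49, 9.59 and 8.38 on the 3 days, and Uty was higher than on day 10 by at least 3.51 and 2.35 on days 12 and 14, and Kdm5d by 2.25 and 1.33. The explanation set first was mice of different sex in the pools, and Xist argued against it, differing by only −0.25 between day 12 and day 10. That test looked for a large drop of Xist, as from a pool of females replaced by a pool of males. Scaling is argued against by a median Y-linked difference of 3.51 that remained after cyclic loess. All 3 measured Y-linked genes stood higher in both later pools, which goes with more male RNA there than on day 10. Whether it came from male mice or male tissue among females stays open. In the day 12 pool Xist was lowest, by 0.23 below the lower of the other days. Xist leaves the day 14 pool undecided, where it differed from day 10 by −0.015 although the Y-linked median was 2.35 higher. A pool with 1 male among 3 mice giving equal RNA would lower Xist by 0.58, a value from arithmetic and not a measurement. Both Xist differences from day 10, −0.25 and −0.015, were smaller in size than that. Because of the Y-linked genes, a sex difference may still accompany every comparison of these pools, and it cannot be told apart from the day.

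The clock genes Dbp, Per1, Per2 and Per3 were higher on day 14 than on day 12, by 0.85, 0.69, 0.66 and 0.79. Scaling is argued against, because their median was 0.75 after cyclic loess. A different hour of tissue collection may be a source, but it cannot be told apart from other sources, since the median of clock genes of the opposite phase was −0.051, with Arntl at −0.44, Clock at −0.03, Nfil3 at −0.08 and Cry1 at 0.13. A further 6 clock genes of the phase of the Per genes had a median of 0.38, with Ciart, Hlf and Tef at 0.60, 0.48 and 0.48, Nr1d2 and Nr1d1 at 0.28 and 0.10, and Bhlhe41 at 0.00. Glucocorticoid targets had a median of −0.020, in the range that had been set before the test to count against glucocorticoid exposure. That exposure is not called excluded here, since its targets went both ways. Zbtb16, Klf9 and Tsc22d3 differed by 0.68, 0.34 and 0.31, and Mt1, Sgk1, Mt2 and Fkbp5 by −0.16, −0.05, −0.03 and −0.02.

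Cornified-layer and sebaceous genes were higher on day 12 and day 14 than on day 10, with medians of 0.54 and 0.55 on day 12. A larger share of epidermis is argued against by 10 basal genes of middle level. Their mean lay below 11, a limit set so that bright probes do not hide a change. The median of these basal genes was 0.0084, with an interquartile range of −0.13 to 0.14. Neighbouring skin with its muscle layer is argued against by muscle genes, whose median was −0.25 above the filter and 0.00 over all 49 measured. The muscle result is weak, since only 7 genes passed the filter, and Des among them is also in the pericyte and smooth muscle list. Over all 49 the interquartile range was 0.00 to 0.00, and equal values are not a precise measurement of no difference. Neighbouring skin without muscle stays open, although dissection was meant to avoid it, since the adipocyte, Schwann cell and hair shaft lists all lay at percentile 99.6 or above on day 12 against day 10, but this rests on the 7 of 21, 10 of 20 and 9 of 35 measured members above the filter, with medians of 0.00, 0.09 and 0.09 over all measured members, and on genes such as Fa2h and Mt4 that sebaceous or epidermal cells also make. Mice of different sex are argued against as the whole source for the cornified genes, whose median between day 12 and day 14 was 0.065 at percentile 100 while that of the Y-linked genes was −1.16, but not for the sebaceous genes, whose median was −0.090 and turned to 0.036 under the filter on the top 25%. Maturation of the new epidermis with time after wounding, the difference the design names, was not tested separately and remains a hypothesis.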
